A study of Mus musculus with 24 samples.

How the data were processed

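Total RNA of 24 samples of mouse mammary tumours grown in BALB/c hosts was extracted with Trizol and measured by NanoString barcode counting, per the labels. The values deposited by the authors are log2 values, 1 column per sample. Checked on the values, 2 to the power of each value, divided by 1 factor per sample, is a whole number within 0.001 for 100% of the values, so the authors' unit is log2 of a barcode count times a per-sample factor. The rule behind that factor, any background subtraction and the image processing are not given in the sources used here. The table has 784 rows, of which 34 hold no value in any sample (14 control probes and 20 genes) and were not analysed here, which leaves 750 genes. Of these, 744 symbols match the mouse gene annotation directly and 6 only as synonyms. Values ran from -2.97 to 14.87, and 322 were below 0.

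Whole counts were recovered with the smallest factor per column that makes every value whole, and their sum over the 750 genes is the total count of a library, 5262 to 1110314. The recovery was tested on simulated data and found the factor in 24 of 24 columns. The background of a library was taken from the 75 genes with the lowest mean count in deep libraries, and its detection limit is the mean plus 2 SD of their log2 values. Their mean count per library was 3.77 to 17.43. Libraries with at least 100000 counts are called deep, a limit chosen after the data were seen. A gene is called expressed if it exceeds the limit in at least 8 of the 16 deep libraries, which 568 genes did. Limits of detection cover counting error and background only.

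Samples were grouped by the infiltrate class in the labels (13 inflamed, 4 excluded, 7 desert), by the leading letter of the sample code, which the labels tie to tumour origin (6 letters), and by whether the code carries 0 (5) or F2 (19). Replicate numbers follow the order of the samples within a class. Samples that share a code number may not be independent tumours: desert replicates 3, 4 and 6, excluded replicates 2 and 3, and inflamed replicates 3 and 4. Where they are not, p values measure only the spread between these samples. Counts of desert replicates 3 and 4 agree within sampling noise, so they were averaged in the class means and SD of genes. The limma fits and the list tests keep all 24 samples, as set before the data were examined, with that average as an alternative.

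Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, 1 term for the groups, all 24 samples), 2-sided, with Benjamini-Hochberg adjustment over the 750 genes and a threshold of 0.05. Letters and the 3 classes together were tested with limma's moderated F test. Levels are means ± SD and differences are fitted log2 differences with their SE. The 24 gene lists (421 genes, of which 248 are measured) were fixed before the data were examined, as were the tests, the rule for named genes and most alternatives. The 22 lists with at least 3 measured members were scored per sample as the mean of their centred members and compared by a 2-sided exact permutation test of class labels, adjusted over the 22 lists of a comparison. The adipose tissue and housekeeping lists, with 2 members each, were not tested. Their medians in inflamed against desert tumours over all libraries are -0.16 for adipose tissue, with Pparg at 0.14 (-0.60 with quantile normalisation) and Cd36 at -0.47, while the housekeeping genes Eif2b4 and Hdac3 differed by 0.48 and -0.15 (Hdac3 by 0.18 with quantile normalisation). Camera with its preset and with an estimated correlation and fry were run beside the permutation test.

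The rule for named genes took the genes past the threshold with the largest changes (10 in each direction for inflamed against desert, 5 for the other comparisons), or the 3 with the smallest p where fewer than 3 passed. It also took the 10 smallest p for letters, up to 4 members of each list with the smallest p in inflamed against desert, and 10 immune genes fixed by name. S100a8, Hdc, Cxcl2, Epcam and Lamb3 in deep libraries, Rsad2, Irf7 and Isg15 in inflamed against excluded tumours, and the genes passing over a list alone were singled out after their values were seen.

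Alternatives covered the origin letter as a random or fixed block, averaging by letter and class or by code number, F2 codes only, recentring on the sample median or the housekeeping list, quantile normalisation, leaving out the genes with the lowest mean values (562 kept), a pseudocount of 10, a trended and robust variance, fits to only the classes compared, and leaving out each sample or letter in turn. Added after the data were seen were the deep libraries alone, with or without inflamed replicates 3 and 4, with expressed genes only or with a letter block, desert replicates 3 and 4 averaged, voom weights on recovered counts and limma array weights (statmod 1.5.0). Some of the array weight fits gave a warning that they stopped before convergence.

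A self-test added known changes to 200 genes of simulated log2 values, drawn with the means and residual SD of the real genes, in 20 simulations. Between inflamed and desert samples, 24.5% of genes changed by 1 log2 unit, 67.2% changed by 2 and 86.7% changed by 3 were called over 24 libraries, and 29.2%, 75.4% and 93.5% over the 16 deep ones. False calls made up 3.5% and 4.03% of the calls. Between code series, 19.3%, 65.2% and 85.5% were called over 24 libraries. These gene simulations drew each gene independently, with the same SD in every library. They leave out correlation between genes and differences in depth, so their rates need not hold for the real data. For lists, 31.8% were called at a shift of 1 and 75.0% at 2, with 0 of 220 called without a shift. The exact test matched an independent enumeration in 30 of 30 draws. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.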

Results

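The data are NanoString counts, which record labelled probes bound to each RNA without amplification, from 24 samples of mouse mammary tumours. Samples that share a code number may not be separate tumours. The tumours grew as mammary tumour-derived transplants in BALB/c hosts. Per the labels, 13 samples carried an inflamed immune infiltrate, 4 an excluded infiltrate and 7 were immune deserts, and the labels do not say how the class was assigned. If it was assigned from these values, the class comparisons are circular. In common use, an inflamed tumour holds lymphocytes among its tumour cells, an excluded tumour holds them at its margin and a desert holds few. The sample codes begin with a letter tied to tumour origin, with 5 samples of A, 6 of C, 2 of F, 4 of G, 4 of H and 3 of L. Class and letter overlapped: all 4 samples of H were inflamed, both samples of F were desert, and the 6 samples of C comprised 4 desert and 2 excluded samples. The codes also fall into 5 samples that carry a 0 after the letter and 19 that carry F2, terms that the labels do not explain. Values of 750 genes, given by symbol, were present in every sample on a log2 scale.

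Depth differed widely among the samples. The total count recovered from the values ran from 5262 to 1110314, a 211-fold range. In 16 libraries the total was at least 100000, and these are called deep here: 8 inflamed, 3 excluded and 5 desert. In the 8 shallow libraries (5 inflamed, 1 excluded and 2 desert) the total was at most 46603. The detection limit of a library, set from its 75 lowest genes, lay between 1.67 and 4.32 log2 units in deep libraries and between 5.14 and 8.40 in shallow ones. Deep libraries had 471 to 613 genes above the limit, and shallow libraries 26 to 427. Of the lymphocyte genes, Cd8a (a chain of the CD8 co-receptor) exceeded the limit in 4 of the 16 deep libraries and Cd3e (a chain of the T cell receptor complex) in 6. Foxp3, the regulator of regulatory T cells, Cd8b1 and Ifng exceeded it in 0. Low values of these genes were therefore not detectable at this depth, which does not show that the RNA was absent. Desert replicates 3 and 4, which share a code number, agree within sampling noise (chi-square 99.5 on 106 degrees of freedom, p = 0.66, over 107 genes). Only 34 and 26 genes exceeded the limit in them, so this agreement rests largely on counts near the background. Desert replicate 6, a deep library of the same code number, differed from both. Its chi-square per degree of freedom was 69.23 and 66.55, and its correlation across genes 0.187 and 0.201. Desert replicates 3 and 4 are counted as 1 sample in the class means of genes below, and separately in the tests.

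**Figure D1:**
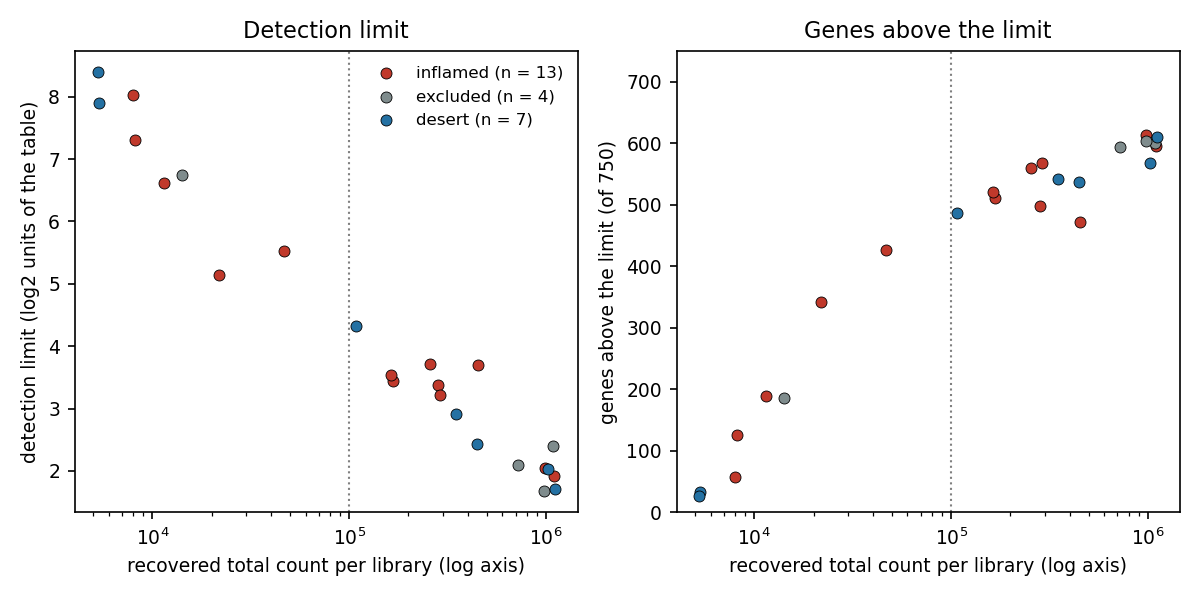
Left, detection limit (log2 units) and right, number of genes above it, each against the recovered total count per library (log axis), with 1 point per library coloured by infiltrate class and a dotted line at 100000 counts. The 16 libraries right of the line had limits of 1.67 to 4.32 and the 8 left of it limits of 5.14 to 8.40.

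The comparison of inflamed with desert tumours asks which genes go with the presence of an immune infiltrate. In the 16 deep libraries, S100a8, which encodes a calcium-binding protein abundant in neutrophils, stood at 6.93 ± 1.45 log2 units (SD, n = 8) in inflamed tumours and at 10.12 ± 0.58 (n = 5) in desert tumours. All 8 inflamed values (5.33 to 9.27) lay below all 5 desert values (9.50 to 10.91). Hdc, the histidine decarboxylase that makes histamine, stood at 2.56 ± 0.75 and 4.85 ± 0.88, and 7 of 8 inflamed values lay below every desert value. The inflamed values of Hdc (1.48 to 3.97) and of Cxcl2 (1.45 to 3.86) lie near the detection limits of these libraries, 1.91 to 3.71. The size of these 2 differences therefore depends partly on the background. With limma, S100a8 (-3.19, SE 0.61) and Hdc (-2.30, SE 0.43) were lower in inflamed deep libraries, each at an adjusted p of 0.0243. S100a9, the partner of S100a8, differed by -3.54 (SE 0.86, adjusted p = 0.135), and the neutrophil-attracting chemokines Cxcl2 and Cxcl1 by -2.15 (SE 0.50) and -2.27 (SE 0.72) without passing the test.

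Over all 24 libraries, limma called 0 of 750 genes between inflamed and desert tumours, with 39 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.326. The voom weights called 5 genes and array weights 5. The smallest p values belonged to Cxcl2 (-2.23, SE 0.55), Hdc (-1.91, SE 0.51) and Areg, which encodes the growth factor amphiregulin (-2.45, SE 0.69), and none of them passed. S100a8 differed by -1.96 (SE 0.81, adjusted p = 0.566) when the shallow libraries were included, and by -0.95 (SE 1.01, adjusted p = 0.812) when these values were quantile normalised. The restriction to deep libraries was chosen after the data were seen, and 5 of 100 splits of the 13 deep libraries, the real one included, gave at least 2 genes. These splits can part samples of 1 code number, which the real grouping keeps together. Without inflamed replicates 3 and 4, which share a code number, the deep difference was -2.67 (SE 0.54) for S100a8 and -2.25 (SE 0.47) for Hdc, both at an adjusted p of 0.0972. In this pair the expressed genes of the macrophage and monocyte list averaged 5.71 to 5.78, against 6.66 to 9.20 in the other 14 deep libraries, and those of the neutrophil list 3.20 to 3.39, against 4.65 to 6.66. Across 49 alternative settings the adjusted p ran from 0.00579 to 1.0 for S100a8 and from 0.00881 to 1.0 for Hdc.

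**Figure D2:**
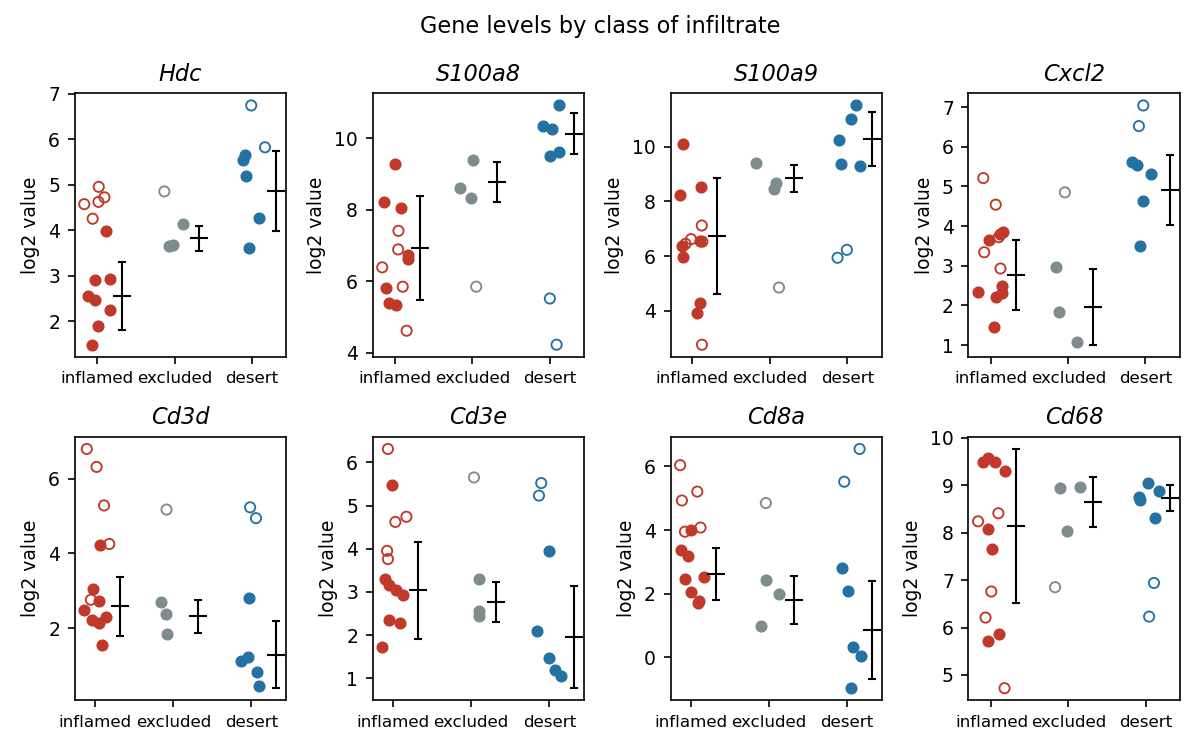
Log2 values of selected genes by infiltrate class, 1 point per library, filled for deep and open for shallow libraries, with bars for the mean ± SD of the deep libraries (8 inflamed, 3 excluded, 5 desert). In deep libraries the S100a8 values of inflamed tumours end at 9.27, below the lowest desert value of 9.50.

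Gene lists fixed in advance were compared as the mean of their centred members. The neutrophil list was lower in inflamed than in desert tumours by a difference of -1.05 (exact permutation p = 0.0151, adjusted p = 0.331), with 7 of its 8 members lower and 0 higher. In deep libraries its difference was -1.30 (exact p = 0.00466, adjusted p = 0.103), with 6 members lower and 2 higher, and 4 members passed when adjusted over the list alone: S100a8, S100a9, the chemokine receptor Cxcr2 and the decoy interleukin-1 receptor Il1r2. Against all genes, 1 of the 4 passed. Inflamed replicates 3 and 4, which share a code number, entered this test as separate samples. With members centred over all 24 libraries, their neutrophil scores were -2.04 and -2.07. The other deep inflamed libraries scored -1.09 to 0.43 and the deep desert libraries 0.11 to 0.84, so the pair carries part of this difference. The myeloid chemokine and cytokine list differed by -0.52 over all libraries, with 17 of 23 members lower. Among them were Il1b (-1.24) and Ptgs2, which encodes cyclooxygenase-2 (-2.96, SE 1.06). The mast cell list, which holds Hdc, differed by -0.64 over all libraries. Its member Cpa3, a mast cell carboxypeptidase, stood at -0.40 (0.15 with quantile normalisation) and Fcer1a, a chain of the IgE receptor, at -0.80. The macrophage and monocyte list differed by 0.20 over all libraries. In deep libraries alone, Cd68, a macrophage marker, stood at 8.15 ± 1.62 in inflamed and 8.74 ± 0.28 in desert tumours. None of the 22 lists passed the adjusted permutation test over all libraries (adjusted p 0.331 to 0.935) or in deep libraries (0.103 to 0.959).

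Lymphocyte and antigen presentation lists had positive differences in inflamed against desert tumours, and none passed. The T cell list differed by 0.52 over all libraries and by 0.87 in deep ones (exact p = 0.0264, adjusted p = 0.291), where 14 of 14 members were higher and 5 of the 14 are expressed. Of the 14, Cd3d, Cd6 and the T cell kinase Zap70 passed in deep libraries when adjusted over the list alone, and 0 passed over all genes. Cd3d exceeded the detection limit in 5, Cd6 in 2 and Zap70 in 8 of the 16 deep libraries, so many of the values compared lie at the background. Cd8a differed by 1.78 (SE 0.59, adjusted p = 0.315) in deep libraries. Of its inflamed values, 3 of 8 lay above every desert value and 8 of 8 above the desert mean. Its inflamed values (1.71 to 3.99) and desert values (-0.97 to 2.81) lie near or below the detection limits. Those limits ran from 1.91 to 3.71 in inflamed and from 1.71 to 4.32 in desert deep libraries. The Cd8a and T cell list differences in deep libraries may therefore depend partly on the background. The CD8 and cytotoxic lymphocyte list differed by 0.33, the CD4 and regulatory T cell list by 0.32, the immune checkpoint list by 0.17, the B cell and plasma cell list by 0.25 and the lymph node list by 0.09 over all libraries. In the T cell list and each of these, all 8 shallow libraries scored above 0 and most deep ones below it. These differences over all libraries therefore mix depth with class. Of the members, 7 of 15 are expressed in the CD8 list, 3 of 11 in the CD4 list and 1 of 8 in the B cell list. With quantile normalisation the CD8, CD4, B cell and lymph node lists turned to -0.05, -0.04, -0.01 and -0.11. The MHC class I antigen presentation list differed by 0.47 with 12 of 13 members higher, among them Psmb9, a subunit of the immunoproteasome (1.23, SE 0.39, adjusted p = 0.339), and the peptide transporter gene Tap1 (0.91, SE 0.36). The MHC class II antigen presentation list differed by 0.95 with 9 of 9 members higher, among them Cd74, the invariant chain (2.05, SE 0.83), and H2-Ab1 (1.64, SE 0.69). The dendritic cell list differed by 0.38 and the lymphocyte chemokine list by 0.43, the latter with Ccl5 at 0.58 and Cxcl9 at 1.04.

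The remaining lists of inflamed against desert tumours had differences of both signs. The interferon gamma response list differed by 0.06 and the type I interferon response list by -0.09. The endothelium and angiogenesis list differed by -0.36, with Angpt2, an antagonist of the Tie2 receptor, at -1.03 (SE 0.32, adjusted p = 0.326). The TGF-beta and stroma list differed by -0.02, the epithelial and mammary tumour list by 0.58, the proliferation list by 0.13, the complement list by -0.12 and the Toll-like receptor list by -0.13. Except for the endothelium and epithelial lists, each of these lists had the opposite sign under at least 1 of the 3 scaling alternatives. Camera with its preset correlation called 7 lists in this comparison, the T cell, neutrophil, both MHC lists, both chemokine lists and the endothelium list. With an estimated correlation 0 were called, at a smallest adjusted p of 0.478.

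**Figure D3:**
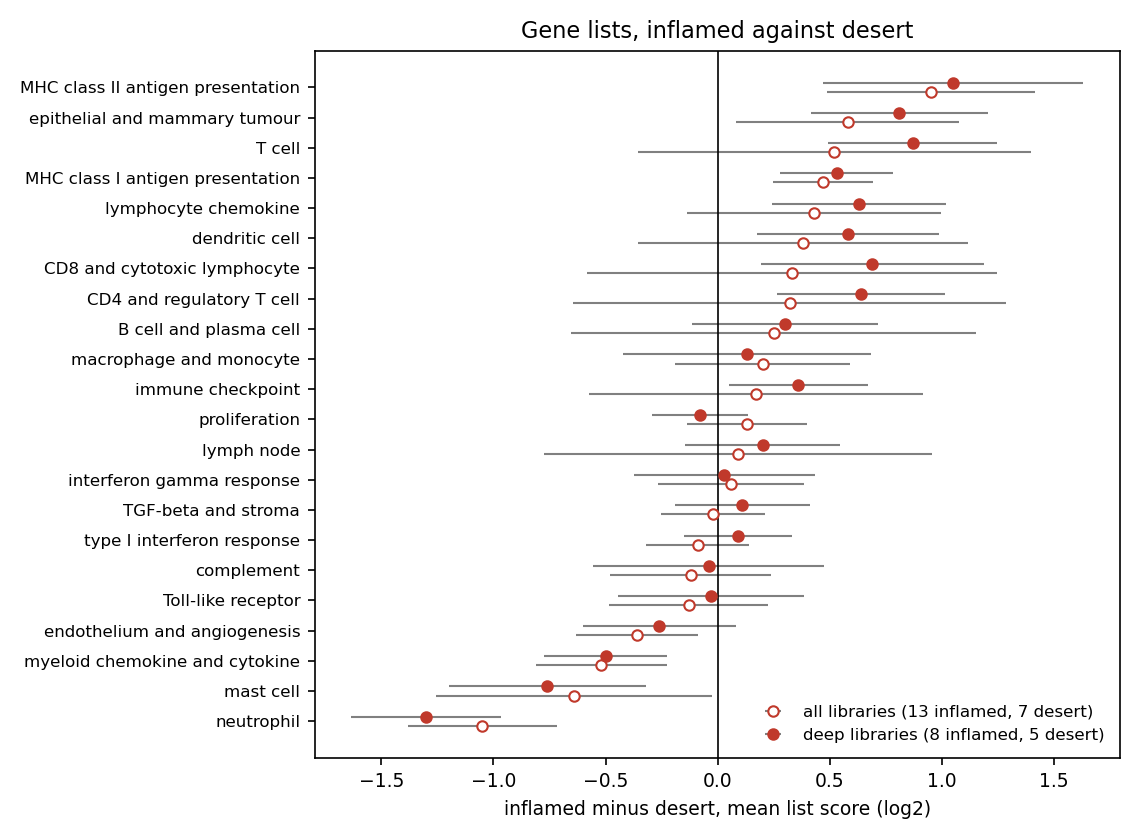
Difference of list scores between inflamed and desert tumours (log2 units, mean of centred members) for each tested list, open points for all libraries (13 inflamed, 7 desert) and filled points for deep libraries (8 inflamed, 5 desert), with bars for ± SE. The neutrophil list lies lowest, at -1.05 in all and -1.30 in deep libraries, and the MHC class II list highest, at 0.95 and 1.05.

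The comparison of inflamed with excluded tumours asks what goes with the place of the infiltrate. Cxcl12, a chemokine made by stromal cells that attracts cells bearing Cxcr4, stood at 8.36 ± 1.30 log2 units (SD, n = 13) in inflamed and 5.38 ± 0.86 (n = 4) in excluded tumours. Its difference was 2.98 (SE 0.69, adjusted p = 0.168) and did not pass. Ifit3, an antiviral gene induced by interferon, differed by -1.34 (SE 0.43) and Anln, a cytokinesis gene, by -1.37 (SE 0.48), both at an adjusted p of 0.973. The type I interferon response list differed by -0.76 (exact p = 0.0168, adjusted p = 0.37), with 17 of 18 members lower in inflamed tumours. Among them were Rsad2 (-1.30, SE 0.50), Irf7 (-1.46, SE 0.60) and Isg15 (-0.96, SE 0.41). The 4 inflamed samples of letter A scored -1.04 to -0.38, and inflamed samples of other letters -0.15 to 0.49. Excluded replicate 1, also of A, scored 1.24, and the other excluded samples 0.38 to 0.41. Outside letter A the classes therefore overlapped, and much of the difference rests on samples of A. The B cell and plasma cell list differed by 1.09 over all libraries and by 0.95 in deep ones (exact p = 0.0121, adjusted p = 0.267), with 8 of 8 members higher. Of these members 1 is expressed in deep libraries and 4 belong to the genes that set the background. The detection limit of deep libraries ran from 1.91 to 3.71 in inflamed and from 1.67 to 2.40 in excluded tumours, so the score largely compares values at the background.

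In this comparison limma called 0 genes, with 25 at an unadjusted p under 0.05, voom weights called 0 and array weights 269. Those weights gave excluded replicate 3, which shares a code number with excluded replicate 2, a weight of 34.6, and some of their fits stopped before convergence. Without inflamed replicate 5, 1 gene was called, Cxcl12 (3.20), whose adjusted p ran from 0.000146 to 0.999 over the alternatives. None of the 22 lists passed (adjusted p 0.37 to 0.982). Camera with its preset correlation called the type I interferon and B cell lists, and 0 with an estimated correlation, at a smallest adjusted p of 0.163. Quantile normalisation and centring on the housekeeping list each carried the type I interferon response list past the threshold, at -0.68 and -1.11 (adjusted exact p = 0.037 in both). The housekeeping list holds only 2 measured genes. Whether these calls rest on the samples of letter A was not tested.

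Excluded and desert tumours were compared to ask what separates tumours with a marginal infiltrate from those with few lymphocytes. Cxcl2 was 2.69 ± 1.64 log2 units (SD, n = 4) in excluded and 5.23 ± 1.10 (n = 6) in desert tumours, a limma difference over 11 libraries of -2.76 (SE 0.73, adjusted p = 0.698). Cxcl3, a related chemokine, differed by -2.70 (SE 0.93) and Ifit3 by 1.54 (SE 0.47), and neither passed. The neutrophil list differed by -0.71 (exact p = 0.0121, adjusted p = 0.267), with 8 of 8 members lower in excluded tumours. The type I interferon response list differed by 0.67 (exact p = 0.0485, adjusted p = 0.489), with 16 of 18 members higher. In deep libraries its difference was 0.96 (exact p = 0.0357, adjusted p = 0.262), and Ifit3, Oas2 and Oas3, which sense or restrict viral RNA, passed when adjusted over the list alone, with 0 over all genes. The myeloid chemokine and cytokine list differed by -0.75 and the MHC class I antigen presentation list by 0.48.

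Between excluded and desert tumours limma called 0 genes, with 18 at an unadjusted p under 0.05, voom weights called 1 (Cxcl2, -2.87) and array weights 115. None of the 22 lists passed (adjusted p 0.267 to 0.933). Camera with its preset correlation called 3 lists, the type I interferon, MHC class I and myeloid chemokine lists, and 0 with an estimated correlation, at a smallest adjusted p of 0.243. A single test over all 3 classes called 0 genes, with 39 at an unadjusted p under 0.05. Its smallest adjusted p, 0.209, was that of Cxcl12 and Cxcl2. Voom weights called 4 genes in that test, Areg, Cxcl2, Hdc and Twist2, and array weights 282. The 4 excluded samples include a pair that shares a code number, so p values measure only the spread between these samples.

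Tumour-origin letters were compared to ask which genes mark the origin of a transplant. Epcam, an epithelial adhesion molecule, stood at 10.42 ± 0.47 log2 units (SD, n = 3) in the deep libraries of letter A. In the other letters its deep means ran from 1.98 ± 0.46 (C, n = 4) to 3.65 ± 1.06 (H, n = 2). Lamb3, which encodes a chain of a basement membrane laminin, stood at 4.81 ± 1.17 in A, and its means in the other letters reached at most 2.30 ± 0.58 (H). In deep libraries limma's F test called 3 genes, among them Epcam (adjusted p = 2.02e-05) and Lamb3 (adjusted p = 0.0422). Cdh1, the epithelial cadherin, stood at 5.97 ± 2.22 in A and at no more than 2.10 ± 1.95 elsewhere, and did not pass (adjusted p = 0.121). The means of these genes outside A lie within or below the range of detection limits of deep libraries, 1.67 to 4.32. The size of these differences therefore depends partly on the background.

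Over all 24 libraries the F test among letters called 0 genes, with 60 at an unadjusted p under 0.05, and Epcam was closest (adjusted p = 0.0905). Voom weights called 57 genes and array weights 607. The genes with the next smallest p included Irf8, Fosl1, Syk, Zeb1, Ulbp1, Tlr4, Mdm2 and Il34, all at an adjusted p of 0.579. Of these, Zeb1, a repressor of epithelial genes, stood at 5.34 ± 0.75 in A and between 6.98 and 7.18 in the other letters in deep libraries, and Irf8, a regulator of myeloid cells, at 4.11 ± 1.06 in A and 7.25 ± 0.18 in H. The 3 deep libraries of A are excluded replicate 1 and inflamed replicates 3 and 4, a pair with 1 code number. Without that pair 1 gene, Epcam, was called in deep libraries, with the 1 remaining A library assumed to vary like the others. Leaving out desert replicate 3, desert replicate 4, inflamed replicate 5 or excluded replicate 4 from the full set likewise gave 1 call, Epcam, whose adjusted p ran from 7.16e-12 to 0.575 over the alternatives.

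**Figure D4:**
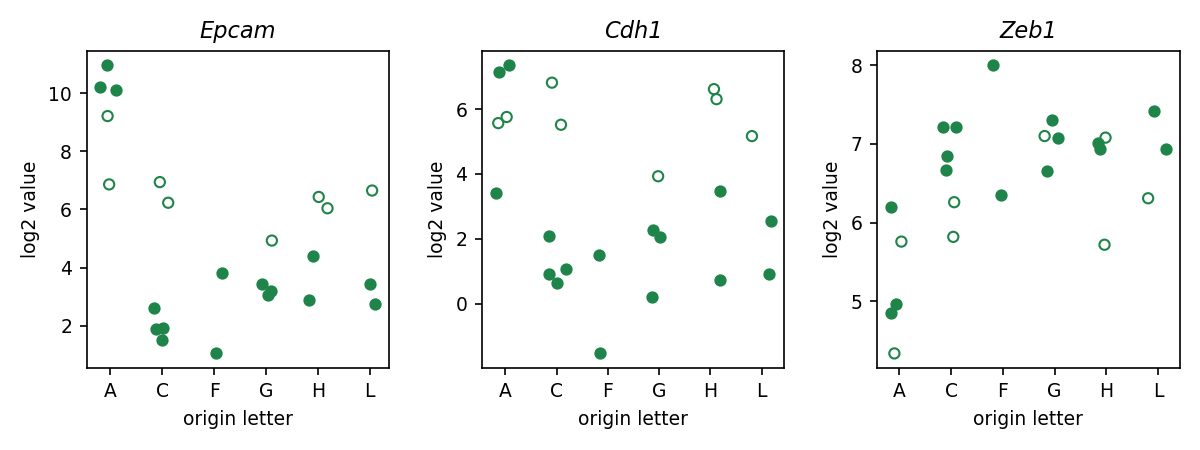
Log2 values of Epcam, Cdh1 and Zeb1 by tumour-origin letter, 1 point per library, filled for deep and open for shallow libraries. Deep libraries of A average 10.42 for Epcam, against 1.98 to 3.65 in the other letters.

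The 5 samples coded 0 and the 19 coded F2 were compared by code alone. Hk2, which encodes the glycolytic enzyme hexokinase 2, stood at 4.10 ± 0.75 log2 units (SD, n = 5) in series 0 and 6.16 ± 0.78 (n = 19) in F2, and rose by 2.06 (SE 0.41, adjusted p = 0.0255). Pecam1, an endothelial adhesion molecule, fell from 8.38 ± 0.52 to 6.67 ± 1.00 (-1.71, SE 0.48). The immediate early genes Dusp1 (-1.86, SE 0.54) and Egr1 (-1.36, SE 0.39) also fell, as did the integrin gene Itgav (-1.32, SE 0.37) and Mfge8 (-1.12, SE 0.32), each at an adjusted p of 0.0432. The largest rises were those of Ifng (4.09, SE 1.02), H2-Pa (4.07, SE 1.10), the cancer-testis gene Magea1 (4.06, SE 0.92), Ccl1 (3.88, SE 1.00) and Il22ra1 (3.86, SE 1.03). These 5 genes were above the detection limit in at most 1 of the 16 deep libraries. Of the T cell list, 13 of 14 members were higher in F2, with a median difference of 1.8. Only 5 of the 14 are expressed in deep libraries, and the mean detection limit was 2.02 in series 0 and 4.74 in F2. The rise of this list therefore cannot be told apart from background scaled up at lower depth. Over all genes 1 member (Cd28) passed, and 8 passed when adjusted over the list alone, Thy1 among them as the 1 lower in F2. In deep libraries the median was 0.6, and 3 members passed over all genes and over the list alone, Cd28 and Sh2d1a higher and Thy1 lower in F2.

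Limma called 36 genes between the code series, 31 higher and 5 lower in F2, and the median of all genes was 0.16 higher in F2. The lowest total of a series 0 library, 982205, exceeds the highest of F2, 976271, so depth and code series cannot be told apart over all libraries. Of the 31 genes higher in F2, 29 lay on average below the detection limit in series 0, against 117 (16.3%) of the other 719. This share is partly fixed by the choice of genes. Genes called higher in F2 tend to be low in series 0, and 18 of the 31 belong to those that set the limit. With only genes above the limit in at least 8 of the 16 deep libraries, 0 genes were called in deep libraries. Class as a further term also left 0 genes, voom weights left 1 (Hk2) and array weights gave 110. Leaving out inflamed replicate 1 or 2, or desert replicate 1 or 2, all of series 0, gave 0 genes. Without excluded replicate 1 the count was 3, without desert replicate 3, inflamed replicate 5, 6, 9 or 12 or excluded replicate 4 it was 1 (Hk2), without inflamed replicate 7 it was 2 and without desert replicate 7 it was 6. It was 84 without excluded replicate 2 or desert replicate 5 and 67 without excluded replicate 3.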

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

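In this part, the tests of splits, of background genes, of the scaling, of inflamed replicates 3 and 4 and of list levels were chosen only after the results were seen, while the depth covariate and the splits that keep samples of 1 code number together were set before their own results were seen. Of 108 group tests on 36 measures, 13 found a sample far from the others of its group, and chance flags about 1 in 20 groups. Most of the 13 are shallow libraries. The log10 total count of excluded replicate 4 was 4.15, against 5.86 for the nearest excluded library. In the same library the list scores were 1.68 for T cells (nearest -0.79), 2.11 for CD4 and regulatory T cells (nearest -1.06), 1.40 for immune checkpoints (nearest -0.91) and 1.63 for mast cells (nearest -1.05), and Cd4 stood at 5.43 (nearest 2.88). Desert replicates 3 and 4, averaged, had scores of 3.17 for CD4 and regulatory T cells (nearest -0.41), 2.44 for immune checkpoints (nearest -0.13) and 2.85 for the lymph node list (nearest -0.61). Their Cd68 was 6.59 (nearest 8.30) and their S100a8 4.88 (nearest 9.50). The type I interferon response score of excluded replicate 1 was 1.24 (nearest 0.41). In code series 0, Pdcd1, which encodes the PD-1 receptor, was 0.73 in desert replicate 2 (nearest 1.63).

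Among the 36 genes that separated code series 0 from F2, 31 were higher in F2, and among them were Ifng, Foxp3 and Magea1. The 31 had a median difference of 3.59, against 0.11 (SD 1.23) for the other 719 genes. The 31 were picked for a large difference, so this contrast cannot decide on the authors' scaling. Over all 750 genes, without that pick, the median was 0.16 higher in F2. This argues only against a shift of all genes alike as large as 3.59. Recentring each sample on its median gave 133 genes higher in F2, and recentring on the housekeeping list or quantile normalisation gave 0. On the housekeeping list the median difference of the 31 was 3.56 while their median SE went from 0.96 to 1.07, and with quantile normalisation it was 1.86 (SE 0.66), so an effect of scaling that differs between low and high genes stays open. Background counts scaled up in libraries of lower depth may account for most of the 31: over the 19 F2 samples, where they are higher, 90.3% of them (28) lay below the mean detection limit of these samples, 4.74, against 32.5% (234) of the other 719 genes. Of the 31, 18 belong to the genes that set the background, and 10 of the remaining 13 lay below the limit. Hk2, Ppargc1b and Cd28 lay above it, and a biological difference between the code series was not tested, since the labels do not define them. Of 100 splits of the 24 samples, 3 gave any call, and these 3, the real one included, gave at least 36 genes, with 338 as the highest other. In deep libraries 6 of 100 gave any call and 3 at least the real 31, with 99 as the highest other. These splits part samples that share a code number, which the real grouping keeps together. Of 100 splits that keep them together, 3 gave at least 36 genes, with 41 as the highest other, and in deep libraries 1 of 100, the real one, gave at least 31, with 23 as the highest other. By these shares, under 0.05, chance is argued against, but 0 genes were called without inflamed replicate 1 or 2 or desert replicate 1 or 2. A split with 338 genes may point to a structure of the samples, which was not tested.

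S100a8 and Hdc were lower in inflamed than in desert deep libraries, 2 called genes. A difference in depth among deep libraries is argued against, since with log10 total count as a covariate 101.6% of the mean difference of both genes stayed (S100a8 -3.22, SE 0.63, and Hdc -2.36, SE 0.43, both at an adjusted p of 0.0392, the range over the alternatives being 0.00579 to 1.0 for S100a8). Inflamed replicates 3 and 4 may set part of it: without them 89.6% of the difference stayed, S100a8 going from -3.19 (SE 0.61) to -2.67 (SE 0.54) and Hdc from -2.30 (SE 0.43) to -2.25 (SE 0.47), and both calls ended at an adjusted p of 0.0972. The smaller number of samples and the smaller difference both act there, so the role of the pair, whose neutrophil list is also the lowest of the deep libraries, cannot be told apart. Of 100 splits of the 13 deep libraries, 5 gave at least 2 genes, the real one included, with 20 as the highest other. These splits can part inflamed replicates 3 and 4, which the real grouping keeps together. Chance therefore cannot be excluded. Only letter G holds both inflamed (3) and desert (1) samples, so class and tumour origin cannot be told apart. In deep libraries limma's F test among letters gave p = 0.0582 for S100a8 and 0.0586 for Hdc (adjusted p = 0.283 for both). A difference between the classes stays open as a hypothesis.

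Inflamed replicates 3 and 4, of letter A, stood apart from the other 14 deep libraries, with highest correlations across 568 genes of 0.698 and 0.697 with a deep library of another code number. Genes are not independent replicates in such a correlation. A low total count is argued against, since 4 deep libraries with smaller totals had a nearest library at 0.882 or more. The mean background counts of the pair, 17.43 and 9.76, were the highest of the 24 libraries, followed by 8.69 in excluded replicate 1. In the pair 471 and 497 genes exceeded the detection limit. A weaker signal over background was not tested as a cause. A lower share of macrophage, stromal and endothelial RNA may play a part: in 3 of 3 lists both lay below every other deep library, at 5.71 to 5.78 against 6.66 to 9.20 for macrophage and monocyte, 6.19 to 6.25 against 6.48 to 7.84 for TGF-beta and stroma, and 5.07 to 5.08 against 5.72 to 7.63 for endothelium and angiogenesis. The low values are not particular to these, as both lay below every other deep library in 13 of 24 lists, among them neutrophil (3.20 to 3.39 against 4.65 to 6.66), complement (5.56 to 5.80 against 7.03 to 9.37) and interferon gamma response (4.45 to 4.50 against 5.22 to 7.46). Tumour origin, which the letter names, stays open. Inflamed replicate 6, a shallow library of A, correlated with the pair at 0.874 and 0.876, but inflamed replicate 5, which is shallower, and excluded replicate 1, which is deep, both also of A, at 0.534 to 0.537 and 0.686 to 0.692.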

How the results depend on the processing

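In this part, the deep-library settings, the average of desert replicates 3 and 4, voom weights and array weights were chosen only after the results were seen. No result turned its direction past the threshold. Inflamed against desert, 0 genes in the fit reported, gave 1 gene with quantile normalisation (Cxcl2), 2 in deep libraries, 2 there with expressed genes only and 2 with the letter as a random block (Hdc and S100a8 each time), 5 with voom weights (Areg, Hdc, Twist2, Cxcl2 and Tnfrsf9) and 5 with array weights (S100a8, S100a9, Hdc, Cxcl1 and Cxcl2). Inflamed against excluded, also 0, gave 1 with quantile normalisation (Cxcl12) and 269 with array weights. Excluded against desert, also 0, gave 1 with voom weights (Cxcl2) and 115 with array weights. The test over 3 classes, also 0, gave 2 with quantile normalisation (Cxcl2 and Cxcl12), 4 with voom weights and 282 with array weights. Tumour-origin letters, also 0, gave 1 (Epcam) when recentred on the sample median, with quantile normalisation, without the lowest genes by mean value, with a pseudocount of 10, with a trended and robust variance, with desert replicates 3 and 4 averaged and in deep libraries without inflamed replicates 3 and 4. They gave 3 in deep libraries, 1 there with expressed genes only, 57 with voom weights and 607 with array weights. The highest array weights were 34.6 and 4.84 for excluded replicates 3 and 2 in the class fit, 10.4 to 14.8 for these and inflamed replicates 3 and 4 in the letter fit, both pairs that share a code number, and 2.69 for desert replicate 7 in the code series fit. The code series, 36 genes, gave 105 with code numbers averaged and 141 when recentred on the sample median (35 of the 36 genes shared), 110 with array weights, 10 in deep libraries without inflamed replicates 3 and 4 (7 shared), 3 with the letter as a fixed block (Dusp1, Hk2 and Foxp3), 1 without the lowest genes by mean value (Hk2), 1 with voom weights (Hk2) and 1 in deep libraries without that pair and with expressed genes only (Col11a1). It gave 0 when recentred on the housekeeping list, with quantile normalisation, with a pseudocount of 10, with class as a fixed term and in deep libraries with expressed genes only. Deep libraries alone gave 31, of which 21 were shared. Leaving out 1 sample at a time gave 0 to 84 genes for the code series, 0 to 1 for letters, 0 to 1 for inflamed against excluded and 0 throughout for the other class tests and the lists. Lists past the threshold were 7, 2 and 3 by camera with its preset correlation for inflamed against desert, inflamed against excluded and excluded against desert, each of which gave 0 with an estimated correlation (smallest adjusted p 0.478, 0.163 and 0.243), and 1 by the permutation test for inflamed against excluded both when recentred on the housekeeping list and with quantile normalisation (type I interferon response). The cause of these changes was not tested, except that the sets limited to deep libraries hold fewer samples and those limited to expressed genes fewer genes. Recentring moved the median of all genes: on the sample median it lay 0.22 higher in inflamed than in desert and 0.20 higher than in excluded tumours, and on the housekeeping list at -0.16 and -0.29, and 0.12 higher in excluded than in desert tumours. Of the values of 141 single-gene results under the alternatives, 6026 kept their side of the threshold, 63 passed it anew, 221 lost it and 309 took the opposite sign with the test passed in neither. Of the 66 list results, 1635 kept it, 2 passed it anew and 202 took the opposite sign without passing. Depth limits the low genes: only 26 to 427 genes exceeded the detection limit in shallow libraries.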

Other observations

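In this part, the tests of profile similarity and of splits were chosen only after the results were seen, as were the genes named. None of the next 3 genes passed limma's test among origin letters in deep libraries. Their values below leave out the shallow libraries of A, which may differ. The deep libraries of A include inflamed replicates 3 and 4, which share a code number. Sox2, a stem cell factor, stood at 1.70 ± 0.48 log2 units (SD, n = 3) in A, against 5.20 ± 0.49 (H, n = 2) to 7.74 ± 1.18 (C, n = 4) in the other letters (adjusted p = 0.0948). Sox10, a neural crest factor also found in mammary epithelium, stood at 6.85 ± 1.93 in A and at no more than 2.61 (mean of L, n = 2) elsewhere (adjusted p = 0.104). Prom1, a membrane protein used as a stem cell marker, stood at 5.41 ± 0.99 in A and at no more than 2.04 ± 1.22 (H) elsewhere (adjusted p = 0.0948). Sox2 in A, and Sox10 and Prom1 in the other letters, lie within or below the range of deep detection limits, 1.67 to 4.32. The size of these differences therefore depends partly on the background. The complement gene C1qa, made by macrophages, was abundant in all 3 classes of deep libraries, at 10.62 ± 1.88 (n = 8) in inflamed, 11.22 ± 0.85 (n = 3) in excluded and 10.64 ± 0.64 (n = 5) in desert tumours. Mki67, a marker of cycling cells, stood at 9.64 ± 0.68, 10.08 ± 0.18 and 9.27 ± 0.32.

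Libraries of 1 origin letter may resemble each other more than libraries of other letters. Over 14 deep samples, with samples of 1 code number averaged, the mean correlation across genes was 0.824 within and 0.805 between letters (1-sided permutation p = 0.184), which leaves the question open at these numbers. Libraries of 1 infiltrate class were compared in the same way, with 0.806 within and 0.808 between classes (p = 0.474). Among deep libraries, the nearest with another code number shared the letter for 0 of 16 and the class for 6. With shallow libraries as candidates too, it shared the letter for 2, inflamed replicates 3 and 4, and the class for 6. A term for class by code series was fitted to the inflamed and desert libraries only. In it, series 0 is held by inflamed replicates 1 and 2 and desert replicates 1 and 2 alone. It called 0 genes with limma (smallest adjusted p 0.997 at all depths and 0.937 in deep libraries). In these fits 7 and 22 genes had an unadjusted p under 0.05, and no other tool was run.

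Splits of the samples into groups of the same sizes were counted beside each class result. For inflamed against desert, excluded against desert and the 3 classes together, 2, 1 and 2 of 100 splits gave any call, and the highest other splits gave 96, 279 and 218 genes. For inflamed against excluded, 0 splits gave a call. The real counts are 0, which 100 of 100 splits reach by definition, so the splits say nothing about chance. Whether the few splits with many genes reflect a structure of the samples was not tested.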
